A study of Homo sapiens with 2 samples.

How the data were processed

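RNA from LP-1 cells was measured on 2 whole-transcript Affymetrix arrays, 1 of cells with the empty vector and 1 of cells with HIF-2α. The deposited values are log2 signals per probe set, summarised with Affymetrix Expression Console per the submitters' processing notes. The summarisation algorithm, its version and any background correction or centring are not given in the sources used here. The log base was read from the values, since the highest, 13.97, exceeds 11.09, the natural log of the largest 16-bit scanner reading. The scanner files were not used here.

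Of the 28869 probe sets, 21062 carry a gene symbol in the array annotation, 19310 of them a single one. By Entrez number 19279 of these were matched to the RefSeq gene table of GRCh38.p14, which gave only names and the order of genes, and 31 were not. The genome build of the array annotation is not given in the sources used here, so no coordinates are printed. Probe sets with several symbols, 1752 in number, and the 7807 with no listed gene were left out of the gene values. Among these left-out probe sets, 3272 passed the filter below, of which 73 were at least 2-fold higher and 28 at least 2-fold lower in the HIF2A array. Each of 18377 genes took the value of its probe set with the highest mean of the 2 arrays, a choice that concerns 685 genes. A gene entered when its brighter array reached 4.01, the median over probe sets of the mean of the 2 arrays, which 11469 genes did.

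With 1 array per group no test across samples, SE or p-value can be had. Differences are HIF2A minus vector control, and a gene was counted when it differed at least 2-fold. Their spread was summarised by a robust SD, the scaled median absolute deviation. Where an array lay below the 95th percentile of 359 olfactory receptor genes, a fold is given as a bound against that percentile. The median difference of each of 39 gene lists, 30 curated by hand from general knowledge and 9 defined by the pattern of their symbols, was set against the medians of 10000 random lists of the same size, matched by deciles of mean signal, as a description of these arrays. Lists needed 5 genes past the filter. Immunoglobulin segments with 2, mitochondrially encoded genes with 0 and T cell receptor segments were not described; the 1 gene past the filter that matched the pattern for the last, TRADD, is no receptor segment.

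The lists, the counts, the filter, the rule for named genes and most alternatives were fixed before the data were examined. By that rule EPAS1, HIF1A, CCR1, CXCR4 and CXCL12 are named whatever their values, as are the 12 genes with the largest positive and the 12 with the largest negative difference past the filter, leaving out gene families such as histones and small RNAs. Of the 12 higher genes, 1 is not described. In each list up to 3 members with the largest positive and up to 3 with the largest negative difference may be named. XBP1, IRF4, SDC1 and CD38, the genes that bound runs of neighbours and a few genes of the closing section were picked after their values were seen.

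The search for runs of neighbouring genes was chosen after seeing the data. Running medians of 41 genes were taken along each chromosome and compared with the highest such median in each of 1000 shuffles of the gene order, which gave a limit of 0.28. Runs closer than 10 genes were joined and runs under 10 genes dropped. A window of 21 genes was tried first, without a smallest run, and the wider window was taken after its result was seen. With 21 genes and the smallest run, 7 runs with 177 genes were found, on chromosomes 4, 5 and 7, and 174 of those genes lie in the runs reported.

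The alternatives were quantile normalization, median centring and loess centring (span 0.3, 3 robust passes) of the 2 columns, 32 added on the linear scale, no filter or filters at the 25th and 75th percentiles, the mean of a gene's probe sets or its dimmest one, folds of 1.5 and 3, and list means. Chosen after seeing the data were a floor at the olfactory receptor level, leaving out genes in runs, subtracting the median of 20 neighbours, the HIF regulators without EPAS1, and list members in no other list.

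The code was tested on simulated data with 11469 genes and normal errors, with the robust SD of the real differences in each decile of signal. Of 50 genes each, 50 with a true difference of -2, 44 of -1.5, 43 of 1.5 and 49 of 2 came out at least 2-fold in that direction, as did 48 of 11269 genes without a difference in either direction. That SD comes from the same 2 arrays and wider tails were not simulated, so the 48 do not estimate false calls in the real data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.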

Results

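The data are 2 whole-transcript Affymetrix arrays of LP-1, an established human multiple myeloma cell line. In 1 array the cells carried the empty vector pRUF-IRES-GFP, the vector control. In the other, the HIF2A array, they carried the same vector with HIF-2α, the oxygen-regulated transcription factor subunit encoded by EPAS1. Each array gives a log2 signal for 28869 probe sets. The median signal was 4.02 in the vector control, with quartiles of 3.12 and 5.49, and 4.0 in the HIF2A array, with quartiles of 3.08 and 5.52. Pearson's r between the arrays across probe sets, which are not independent replicates, was 0.981. Olfactory receptor genes, taken as a measure of background, had medians of 2.93 and 2.84 and 95th percentiles of 3.59 and 3.58 in the vector control and the HIF2A array. Each group has 1 array, so the differences have no replicate check, and their precision is limited by that number. For 346 genes with more than 1 differing probe set past the filter, the first 2 probe sets could be compared. Their HIF2A minus vector control differences correlated at 0.455 across genes, with a median gap of 0.14 log2 units.

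The comparison asks which transcripts differ between LP-1 cells with added HIF-2α and cells with the empty vector. EPAS1 itself had a signal of 3.70 in the vector control, close to the olfactory receptor level, and 9.05 in the HIF2A array, a difference of 5.35 log2 units or 40.8-fold and the highest of the 11469 genes past the filter on dim signals. HIF1A, which encodes the related subunit HIF-1α, had signals of 6.92 and 6.99, a difference of 0.07. The chemokine receptor gene CCR1 was higher in the HIF2A array, at 6.90 against 4.21, which is 6.45-fold. CXCL12, the gene of a chemokine that retains plasma cells in bone marrow, was 4.63-fold higher, at 6.15 against 3.94, while its receptor gene CXCR4 differed by 0.33, at 7.46 against 7.13.

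Across the 11469 genes the median difference, HIF2A minus vector control, was 0.03 log2 units and the robust SD of the differences was 0.34. Of these genes 89.6% lay within 1.5-fold. At least 2-fold higher in the HIF2A array were 81 genes, and at least 2-fold lower were 84. On the deposited signals 7 genes were at least 4-fold higher. These are EPAS1, CCR1, CXCL12, BNIP3, CNTLN, ARSI and THEMIS, the last with a vector control signal in the background range, which bounds its fold at 3.03. At least 4-fold lower were 3 genes, ALDH7A1, SLAMF7 and S100A10.

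BNIP3, a mitophagy gene and HIF target, had a signal of 8.56 in the HIF2A array against 6.49 in the vector control. TXNIP, which encodes an inhibitor of glucose uptake, had 8.54 against 6.61, and the steroid sulfatase gene STS had 7.99 against 6.30. The centrosomal gene CNTLN had 6.32 against 4.31. The signalling gene THEMIS was below the olfactory receptor 95th percentile in the vector control, so its signal of 5.19 in the HIF2A array is given as at least 3.03-fold higher. Also among the 12 genes with the largest positive differences were ARSI, AK4 and ENC1, with differences of 2.00, 1.93 and 1.75. All 3 lie among neighbours that were also higher, with medians over their 20 nearest measured genes of 0.36, 0.36 and 0.37. AK4 has a further, dimmer probe set, which differed by 0.10.

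ALDH7A1, which encodes a lysine-degrading aldehyde dehydrogenase, was 7.89-fold lower in the HIF2A array, at 4.38 against 7.36. SLAMF7, a plasma cell surface receptor gene, was 5.24-fold lower, at 4.24 against 6.63. S100A10 and ANXA2 encode partners in a cell surface complex that binds plasminogen. S100A10 had 7.33 against 9.61 and ANXA2 had 6.03 against 7.84, and the related gene S100A11 had 6.20 against 7.81. The glutamine synthetase gene GLUL had 5.32 against 7.12, and its other probe set differed by -1.18. The metallothionein gene MT1X had a difference of -1.85, NIBAN1 of -1.70, TUBB2B of -1.66, INHBE of -1.66, RELN of -1.62 and the tumour antigen gene PRAME of -1.62. MT1X, TUBB2B, ANXA2 and BNIP3 have close relatives or pseudogenes, and cross-hybridization of their probes was not analysed here.

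**Figure D1:**
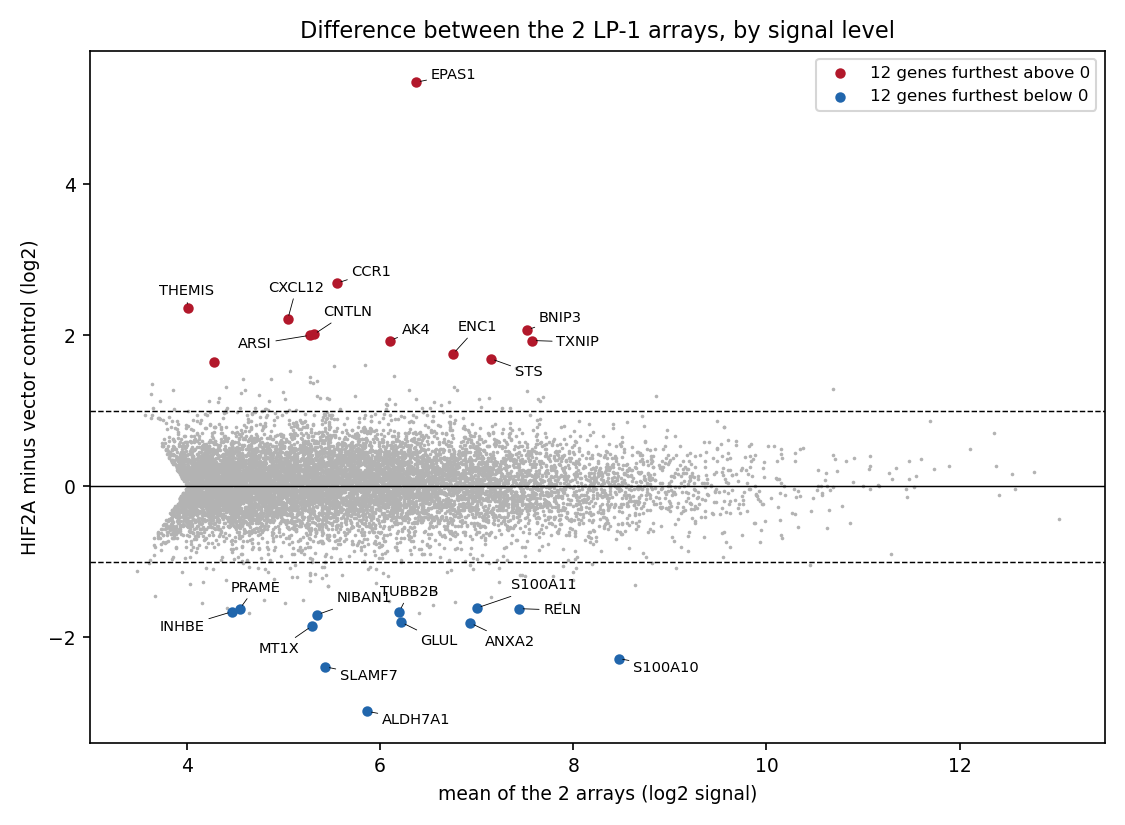
The HIF2A minus vector control difference of each gene past the filter (vertical axis, log2) against the mean of its 2 signals (horizontal axis, log2), with dashed lines at 2-fold. EPAS1 stands apart at 5.35, and the 12 genes furthest above and the 12 furthest below 0 are coloured, all but 1 with their names.

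Genes of glucose uptake and glycolysis known as HIF targets were higher in the HIF2A array as a group. Of the 20 past the filter, 18 were higher and 2 lower, and 11 were at least 1.5-fold higher. Their median difference of 0.61 exceeded the medians of all 10000 random lists matched on signal, whose central 95% ran from -0.17 to 0.20. The pyruvate dehydrogenase kinase gene PDK1 was higher by 1.26, the phosphofructokinase regulator PFKFB3 by 1.17 and the glucose transporter gene SLC2A1 by 0.94. TPI1 and HK1 were the 2 lower members, at -0.33 and -0.12.

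HIF targets outside glycolysis had a median of 0.38 over 30 genes, again above all random lists, with 23 higher and 7 lower. BNIP3, AK4 and the mTORC1 inhibitor gene DDIT4 led them with 2.07, 1.93 and 1.57, whereas the collagen-modifying gene PLOD2 was lower by a difference of -1.18, RORA by -0.37 and HILPDA by -0.30. The 22 members that stand in no other list had a median of 0.19, at the 95.5th percentile of matched random lists and so within their central 95%. Genes known for preferring HIF-2 in other cells had a median of 0.28 over 14 genes, at the 98.98th percentile. Of these 10 were higher and 4 lower, 2 were at least 1.5-fold higher and 0 at least 2-fold higher. The largest positive differences were ADM at 0.93, CITED2 at 0.65 and SLC11A2 at 0.56. In this list 3 genes stand in no other list, and ADM, CITED2 and SLC11A2 are not among them. That list left the upper tail when 32 was added to each linear value and when no filter was used. A compact tumour hypoxia signature, which shares genes with these lists, had a median of 0.35 over 13 genes, at the 99.6th percentile. Joined, the 4 lists of HIF targets and hypoxia genes held 62 genes with a median of 0.36, of which 46 were higher and 15 lower. The HIF subunits and their regulators had a median of 0.30 over 11 genes, at the 97.7th percentile, and 0.23 at the 92.7th percentile without EPAS1. With EPAS1 it also lay inside the central 95% in 5 of 12 other settings, which are quantile normalization, loess centring, no filter, the 25th percentile filter and the dimmest probe set.

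Beyond CCR1 and CXCL12, genes of migration and adhesion went both ways. The 5 chemokine receptor genes past the filter had a median of 0.28, at the 91.5th percentile, with CCR7 at 0.28, CCR10 at -0.19 and CXCR3 at -0.21. That median came to 0.02 without a filter, -0.04 with the filter at the 25th percentile and 0.055 after subtracting the median of 20 neighbours. The 8 chemokine genes had a median of 0.09, with CCL3 at 0.46 and CXCL1 at -0.35. Among 19 adhesion genes, with a median of -0.02, PECAM1 and the integrin gene ITGB7 were higher by 0.92 and 0.79, while S1PR4 and CD44 had differences of -0.65 and -0.57. Matrix proteases had a median of -0.14 over 10 genes and mesenchymal genes one of -0.06 over 10. Of 8 angiogenesis factors, with a median of -0.17, VEGFA was higher by 0.35, and HGF and VEGFC had -0.62 and -0.52. VEGFC lies among neighbours with a median of -0.57. After subtracting the median of 20 neighbours the angiogenesis factors had a median of 0.17, with 5 higher and 3 lower, so their direction is not settled. Each of these medians lay within the central 95% of matched random lists.

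Cholesterol synthesis genes were lower in the HIF2A array, with a median of -0.34 over 16 genes, at the 0.065th percentile of matched random lists. Of these genes 13 were lower and 3 higher, and 6 were at least 1.5-fold lower. MSMO1 had a difference of -1.53, INSIG1 of -1.31 and HMGCS1 of -0.94. MSMO1 lies among neighbours with a median of -0.45.

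Plasma cell identity genes had no common direction. Besides SLAMF7, the BCMA gene TNFRSF17 was lower, at 7.68 against 8.71, whereas ELL2, LAX1 and MZB1 were higher by 0.66, 0.60 and 0.44. ELL2 and MZB1 lie among neighbours with medians of 0.34 and 0.40. XBP1 differed by 0.34, IRF4 by -0.29, SDC1 by -0.25 and CD38 by 0.06. The median of the 19 plasma cell genes was 0.19, at the 96.3rd percentile, and their mean was -0.02, so median and mean differ in sign. Genes of recurrent myeloma translocations had a median of 0.15 over 10 genes, with MYC at 0.53 and FGFR3 at -0.66. Markers of B cells had a median of 0.15 over 10 genes, T and NK cells -0.07 over 6, myeloid cells 0 over 7, stromal cells -0.10 over 8, and endothelial and erythroid cells 0.10 over 7, all within the central 95% of matched random lists.

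Ribosomal protein genes were higher, with a median of 0.28 over 60 genes, above all random lists, and 46 higher against 14 lower. RPS13 and RPL32 had differences of 1.19 and 1.03, and RPL39L and RPL17 of -1.19 and -0.66. Replication histone genes were lower, with a median of -0.18 over 41 genes at the 0.09th percentile, led by H2AC8 at -1.09 and H2BC8 at -0.82. Small nucleolar RNAs had a median of 0.13 over 105 genes at the 99.4th percentile, which came to the 92.1st percentile with the filter at the 75th percentile of signals. SCARNA9 had -1.04 on its brighter probe set and 0.24 on the other.

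Proliferation genes had a median of 0.01 over 34 genes, with KIF20A at 0.85, among neighbours with a median of 0.28, BUB1 at 0.72, and CCNE2 and PCNA at -0.92 and -0.64. The CDK inhibitor and p53 target genes had a median of -0.07 over 22 genes, with PHLDA3 at -0.90, MDM2 at -0.76 and FAS at -0.71. Unfolded protein and integrated stress response genes had a median of 0.14 over 30 genes. In that list DDIT4, DNAJC3 and HYOU1 were higher by 1.57, 0.92 and 0.82, while PSAT1, ASNS and SLC7A11 had -1.54, -1.27 and -0.69. SLC7A11 lies among neighbours with a median of -0.55. The medians were 0.18 for 17 immediate early genes, with DUSP5 at 1.53, and 0.06 for 16 NF-kB targets, with TNFAIP3 at 1.15. They were 0.09 for 15 BCL2 family genes, with MCL1 at 0.53 and PMAIP1 at -0.99, and 0.18 for 11 iron and heme genes, with FTL at 0.75. Interferon-stimulated genes had a median of 0.21 over 13 genes, which came to -0.09 without a filter, with the filter at the 25th percentile, and without genes in runs of shifted neighbours. Respiratory chain genes had a median of -0.05 over 32 genes, MYC targets -0.04 over 23 and housekeeping genes 0.05 over 16. Small nuclear RNAs had a median of -0.10 over 13 genes, microRNA precursors -0.09 over 52 and olfactory receptors -0.18 over 6. All the medians of this paragraph lay within the central 95% of matched random lists. In other settings 3 of these lists left it: microRNA precursors after loess centring, without genes in runs and after subtracting neighbours, at the 1.84th, 1.5th and 0.72nd percentiles, and, with the filter at the 75th percentile, CDK inhibitor and p53 target genes at the 1.75th and iron and heme genes at the 98.6th. Of 36 lists, 9 lay outside that range, where 1.8 would if each list were a random draw of genes. The lists overlap, and genes of a list may vary together between cultures, which 1 culture per group cannot measure. The 9 are therefore no count in excess of variation between cultures.

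**Figure D2:**
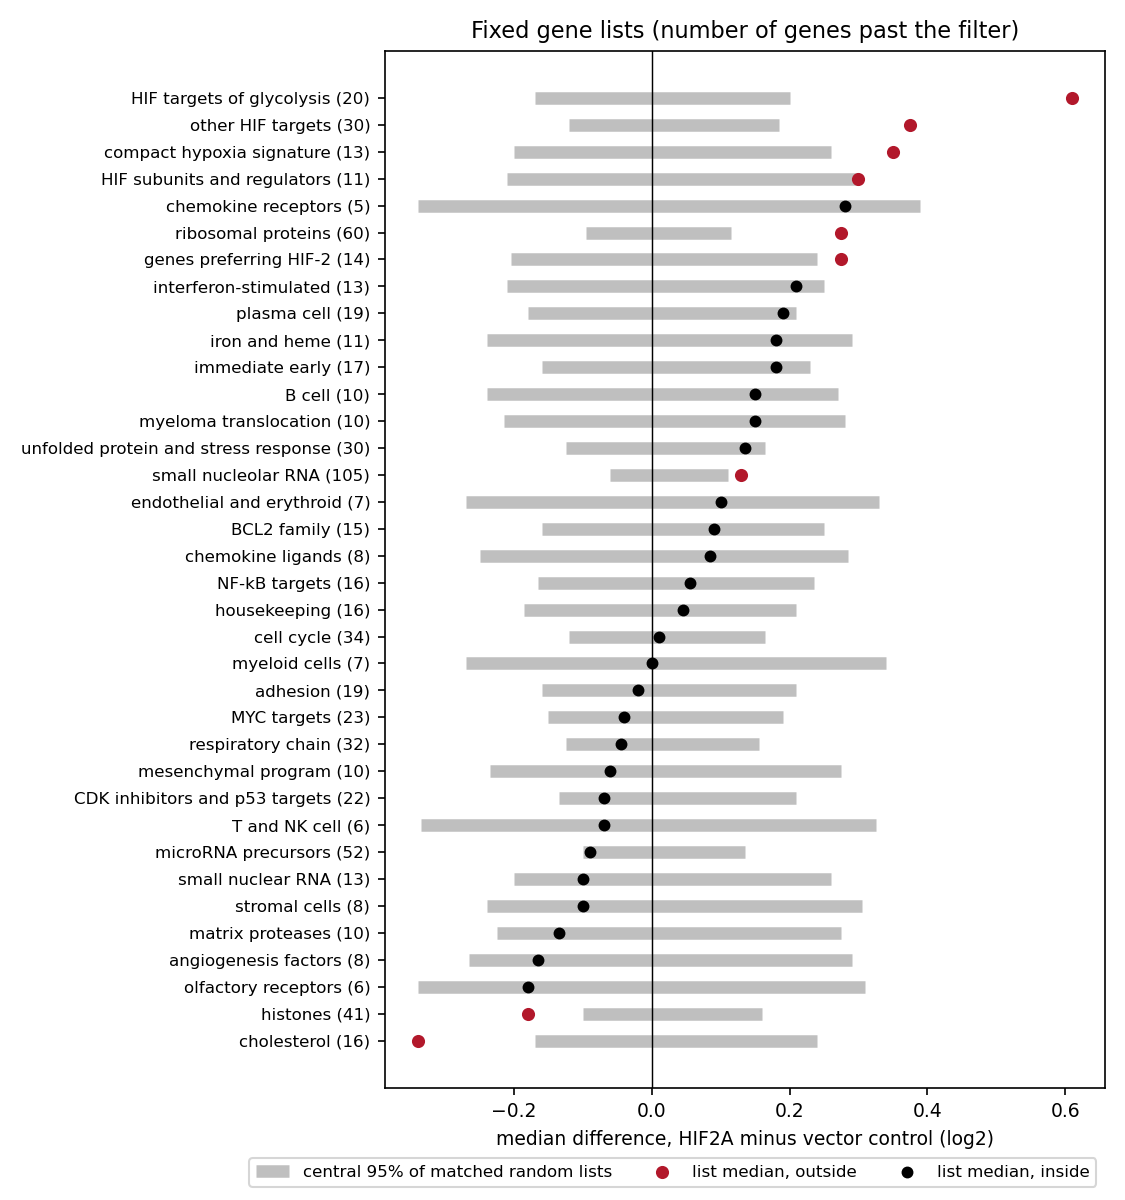
Median HIF2A minus vector control difference (horizontal axis, log2) of each fixed gene list with at least 5 genes past the filter, against the central 95% of the medians of matched random lists (grey bars). HIF targets of glycolysis lie furthest above, at 0.61, and cholesterol synthesis genes furthest below, at -0.34.

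Neighbouring genes on some chromosomes mostly differed in the same direction. On chromosome 4, the 122 genes past the filter from PAPSS1 to TRAPPC11 had a median of -0.46, and 87.7% of them were lower in the HIF2A array. On chromosome 5, the 104 genes from PPWD1 to PGGT1B had a median of 0.33, with 72.1% higher. The 111 from JADE2 to LSM11 had one of 0.39, with 82.0% higher. Chromosome 5 as a whole had a median of 0.28, chromosome 7 one of -0.17, chromosome 8 one of -0.11 and chromosome 4 one of -0.1. Chromosome 11, which holds no run, had a median of 0.16. On chromosome 7, the 109 genes from RPA3 to NIPSNAP2 had a median of -0.33, with 79.8% lower. Shorter runs were the 26 genes from ROR1 to USP33 on chromosome 1, with a median of 0.41, and the 19 from EBAG9 to TBC1D31 on chromosome 8, with one of -0.24, and neither was found with a window of 21 genes. The last run, 19 genes on chromosome 7 from DPY19L2P4 to CASD1, was found from its wider window. It had a median of its own of -0.02, with only 52.6% lower. The 4 lower runs held 2.35% of the genes past the filter and 18 of the 84 genes at least 2-fold lower, and the 3 higher runs held 2.10% and 11 of the 81 genes at least 2-fold higher. ALDH7A1 also lies on chromosome 5, among neighbours with a median of 0.22, opposite to its own difference.

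**Figure D3:**
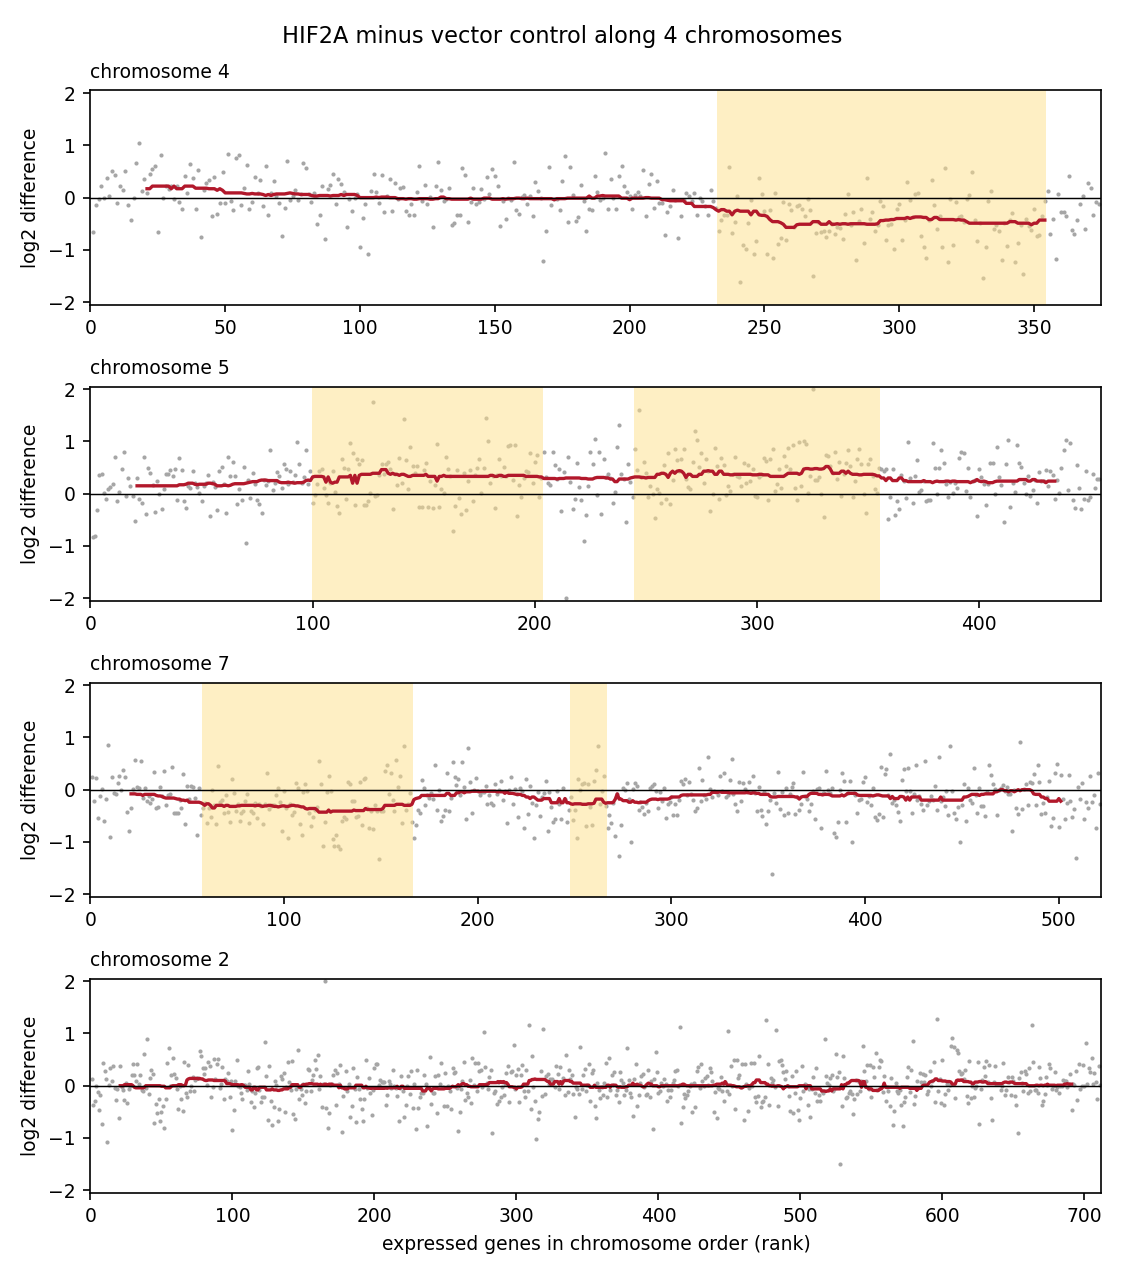
HIF2A minus vector control difference (vertical axis, log2) of each gene past the filter in its order along chromosomes 4, 5, 7 and 2. Red lines are running medians of 41 genes, and shaded stretches are the runs called from them. Points beyond 2 units are drawn at the edge, EPAS1 on chromosome 2 and ALDH7A1 on chromosome 5 among them, and the longest run, on chromosome 4, has a median of -0.46.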

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

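Leaving out members that stand in other lists, dropping or subtracting runs of neighbours, the floor and leaving out EPAS1 were tests chosen after seeing the data. Leaving out a replicate was not possible with 1 array per group. Of 583 values of the 50 named genes at least 2-fold apart, 582 kept their sign, and SCARNA9 came to 0.24 with its dimmest probe set. These genes were picked for large differences in the same 2 arrays, so few changes of sign could arise. Of 2595 values of all named genes, 83 moved by at least the robust SD of the differences. In both counts the filter settings and leaving out genes in runs repeat a gene's value unchanged. The probe set settings can change only genes with several probe sets. Many of these values could therefore not move, and the counts do not measure how stable the genes are. Of 500 list values, 48 moved by at least the SD of the random lists' medians. Adding 32 on the linear scale, which shrinks dim genes by construction, gave 3.64 for EPAS1, 18 genes higher and 24 lower, and medians of 0.44 for HIF targets of glycolysis, 0.23 for the other HIF targets and 0.10 for genes preferring HIF-2. Without a filter the HIF regulators had 0.16, the other HIF targets 0.20 and genes preferring HIF-2 0.09. With the 25th percentile filter the HIF regulators had 0.16 and the other HIF targets 0.21. With the 75th, genes preferring HIF-2 had 0.49. A filter leaves each gene's difference unchanged, so these medians change only with the members that enter. Genes preferring HIF-2 numbered 23 without a filter, 14 with the main one and 7 with the 75th percentile filter. Why dim and bright members differ was not tested. Counts were 650 higher and 546 lower at 1.5-fold, and 14 and 15 at 3-fold. As means, the HIF regulators had 0.73, which includes EPAS1, and cholesterol genes -0.47. Among members in no other list, the other HIF targets had 0.19 at the 95.5th percentile, inside the central 95%, and the hypoxia signature -0.035, the reverse of its direction, over 4 genes, too few for a list. HIF targets of glycolysis, the other HIF targets, the hypoxia signature, cholesterol, ribosomal protein and histone genes kept their side of the random lists' central 95% in each of the 12 settings of scaling, offset, filter, probe set, floor and neighbours, small nucleolar RNAs in 11, genes preferring HIF-2 in 10 and the HIF regulators in 7. Of 27 lists inside that range, 3 left it in some of these settings. Dim signals near background limit the folds of genes such as THEMIS.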

Other observations

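Chosen only after the results were seen were the split of the stress list, the tests of gene order and of loess centring for the runs of neighbouring genes, and the place of the 6 amino acid and stress genes. Within the stress list, 14 genes of ER chaperones and ER-associated degradation had a median difference of 0.25, with 12 higher in the HIF2A array, at the 97.8th percentile of matched random lists. The 16 genes of the amino acid and integrated stress response had a median of 0.05, with 9 higher and 7 lower.

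HIF targets outside glycolysis, BNIP3, AK4 and DDIT4 foremost, were higher in the HIF2A array. A trend of the difference with signal level is argued against, because the median difference by decile of mean signal ran only from -0.02 to 0.07. After loess centring the list's median stayed 4.23 SD above the mean of matched random lists. Those lists were already matched on signal, so this adds little. Without the 3 members with the largest differences the list's median was 0.31, at the 99.9th percentile. A median depends little on its largest members, so that test could hardly have come out otherwise. Of the list's 30 members 23 were higher and 7 lower, so its direction is not that of 3 members alone. Its call does rest in part on members shared with other lists, since the 22 members in no other list had a median of 0.19, at the 95.5th percentile and so inside the central 95%. Runs of neighbouring genes do not account for it either, since without genes in runs it lay at the 100th percentile. Added HIF-2α may raise these transcripts, but oxygen, cell density or any other difference between the 2 cultures was not tested and stays open with 1 culture per group.

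Runs of neighbouring genes, such as that from PAPSS1 to TRAPPC11 on chromosome 4, may reflect a difference in copy number between the 2 cell populations. When runs were called on every other gene, the 2 calls found 5 and 4 runs, against 7 with all genes. Within these runs the 85 and 107 genes left out had pooled medians of 0.37 and 0.38 in the runs' direction. Of them 78.8% and 83.2% lay on that side. The random SD was 0.0453 and 0.0401, which argues against chance order for the runs found in these calls, pooled. Each run on its own was not tested, so chance order stays open for single runs. Loess centring kept 94.5% of the genes in runs. The median difference by decile of mean signal ran only from -0.02 to 0.07, so loess centring could move few genes out and adds little. That range is small beside the medians of -0.46, 0.33, 0.39 and -0.33 of the longer runs on chromosomes 4, 5 and 7. For those runs it argues against a signal-dependent trend. The robust SD within runs was 1.17 times that outside, within the bound set for genes that shift together, as a copy number difference would make most of them do. It was taken around each run's own median, so genes in chance order could meet that bound too. The ratio therefore does not tell a copy number difference from other causes. A shift of only part of the genes is not excluded, the 19 genes from DPY19L2P4 to CASD1 show none, with a median of -0.02, and no DNA measurement was used here. Of the 24 genes with the largest differences, 3 (ARSI, AK4 and ENC1) have neighbours shifted in their direction beyond the 5% tail, where chance gives 1.2 (exact binomial, one-sided p = 0.116, across genes that are not replicates), a count too small to settle whether copy number adds to the largest differences. The medians of their neighbours, 0.36, 0.36 and 0.37, are smaller than their own differences of 2.00, 1.93 and 1.75, but the genes were picked for large differences, and AK4 differed by 0.10 on its other probe set.

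PSAT1, ASNS, SLC7A11, CHAC1, INHBE and NIBAN1, genes of amino acid supply and stress picked because they were lower in the HIF2A array, had differences of -1.54, -1.27, -0.69, -0.57, -1.66 and -1.70. They are no fixed list, and the 16 genes of the amino acid and integrated stress response, with 9 higher, show no common direction. Of the 6, only SLC7A11 lies in a lower run, so the runs found do not account for the set. A copy number difference too short or too mild to form a run would not be seen this way and stays open. Handling before RNA extraction cannot be told apart, because the immediate early genes lay at the 92.9th percentile of matched random lists, inside the bound set for excluding it but by less than the spread of those lists, a margin required only after the value was seen. No biological explanation was tested.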
